A study of Mus musculus with 15 samples.

How the data were processed

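The processed table of the series was analysed, with 12000 mouse genes and 15 libraries, and the raw reads were not analysed here. Groups, times and replicate numbers were read from the sample titles per the labels, and the groups, comparisons and a first set of alternatives were fixed before the data were examined. Per the labels' protocols, messenger RNA was captured on beads, reverse transcribed with samples pooled after first-strand synthesis in amounts set by Actb quantitative PCR, amplified by 17 to 20 PCR cycles, made into strand-specific libraries in 2 final pools and sequenced as 40 and 10 bp paired ends on an Illumina HiSeq instrument. Per the submitters' processing notes, reads were aligned with STAR 2.5.4a, counted with featureCounts and normalized with DESeq2, and the notes name GRCm38 and mm10 without a role for each. No molecular barcode is stated there, so copies made in the amplification were not removed as far as these sources say.

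The deposited values were taken as log2 of a normalized count plus 1, although no unit is stated per the file headers. The base was settled from the values, because the lowest values of each library lie on evenly spaced steps after raising 2 to their power and subtracting 1 (lowest r2 0.994 and median 0.999, against a median of 0.990 for base e and 0.842 for base 10). The sorted values of the 15 libraries coincide at the top, the first 13 ranks being identical, and in the ranks just below they differ by at most 0.019, so the table was taken as quantile normalized. Neither such a step nor the rule that left 12000 genes is given in the sources used here. The highest value is 16.8, the sums of the values on a linear scale lie between 9949400 and 9951600 in every library, and a gene at the top of the scale in 1 group can fall further behind its true amount than others. The design had assumed counts, so tests made for counts did not suit the unit, and the main test was changed to limma on the log2 values with no further offset. The table's own gene symbols were used, and 11967 of 12000 identifiers matched GENCODE vM21 on GRCm38, 11881 of them as protein coding genes. Positions printed in the text are from that annotation. No gene was filtered out, and the planned filter on a mean of at least 1 removed none, because the lowest mean was 1.37.

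Linear models had 1 mean per group (10 residual degrees of freedom) and were fitted with limma 3.58.1 in R 4.3.3, with moderated variances from a robust mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method over 12000 genes with a threshold of 0.05. The 9 comparisons were each stimulated group with unstimulated cells, the stimuli with each other at 3 h and 6 h, 6 h with 3 h for each stimulus, and the difference between stimuli of that change. Errors of log2 changes are the moderated standard errors. Agreement between stimuli was the correlation of log2 changes over the genes. Beside it stood 100 simulations in which the stimuli shared the 3 unstimulated libraries and neither caused any response. Further tools were statmod 1.5.0 for the estimated array weights, Python 3.11.15 and matplotlib 3.10.9 for the figures.

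Gene lists, 31 of them with 25 for pathways and 6 for cell-type markers, were fixed before the data were examined. They are secreted cytokines, chemokines, cytotoxic effectors, immediate early genes, calcium and NFAT targets, NF-kB targets, STAT targets, cytokine receptors, interferon-stimulated genes, activating and inhibitory NK receptors, immune checkpoints, NK transcription factors, migration and tissue egress, glycolysis, amino acid and polyamine metabolism, sterol and fatty acid synthesis, oxidative phosphorylation, ribosome biogenesis, cytosolic ribosomal proteins, DNA replication, mitosis, unfolded protein response, apoptosis and survival, heat shock and dissociation stress, and the markers of B cells, T cells, monocytes with macrophages and granulocytes, dendritic cells, erythroid cells with platelets, and innate lymphoid cells. Each list was tested against the other genes with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data, with p-values adjusted over the 31 lists. Members were also tested one by one, with p adjusted over all genes and, separately, adjusted over the list alone. The fry test was run beside these, and its p tests whether the genes of a set move on balance in 1 direction, without comparing them with other genes.

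Genes were named by a rule. It takes the 8 largest rises and 8 largest falls that passed the test, had a level of at least 10 CPM (counts scaled to a common total) over the libraries compared and did not overlap between groups, which 10% of genes with no change do for 3 against 3 libraries, and 5 of each for the comparisons over time and their difference. Predicted genes and immunoglobulin or T cell receptor segments were left out. In the comparisons with unstimulated cells and between stimuli it adds up to 4 members of each list with the largest changes that passed, or the 2 with the highest means where none did, and in every comparison 22 genes chosen beforehand. Genes that share reads with near-identical copies (Ccl3, Gzmc, Klra8, Bcl2a1b, Ly6a, the Klrb1 family, Lilrb4a, Hba-a1 and Iigp1) are named as uncertain or left out, and the other genes of the rule that are not printed add nothing to the groups described or are not reported here.

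Of that first set, the alternatives that suit the unit were a block for the replicate number, offsets of 0.1 and 5 in place of 1, a fit to the libraries of the groups compared alone, an added limit of 1 on the absolute log2 change, leaving out each library in turn, the estimated correlation and fry. Chosen after the data were seen were median-of-ratios rescaling, array weights, a term for MK, comparison within 1 value of MK, removal of the trend with GC content and transcript length, no mean-variance trend, and genes with a mean log2 value of at least 5. The replicate numbers were checked for pairing by correlating the deviations of libraries from their group means. The median r of 30 pairs with the same number was 0.0212, against 0.00225 for 60 pairs with different numbers, and 6 of 15 libraries matched best with their own number, so the numbers were not treated as pairs.

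The pipeline was tested on 12000 simulated genes, 200 changed, whose spread may differ from that of real groups. Recovery of changed genes was 98.5% to 100% at 4 times, 68.7% to 89.6% at 2 times and 10.4% to 32.8% at 1.5 times. False calls were 1.50% to 16.8% of calls, most for the stimuli compared at 3 h. For the difference between stimuli, recovery at 4 times was 99.5%. Camera found 30 genes raised 2 times in 20 of 20 trials and called 0 of 620 unchanged lists. This may not hold for correlated genes.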

Results

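Gene expression was measured in 15 RNA sequencing libraries of wild-type C57BL/6 mouse natural killer (NK) cells, which the series title places in the spleen. They formed 5 groups of 3: cells left unstimulated and taken at 0.5 h, cells given IL-12 and IL-18 for 3 h or 6 h, and cells given an antibody to NK1.1 for 3 h or 6 h. IL-12 and IL-18 are cytokines that drive NK cells to make interferon gamma, and NK1.1 is the activating receptor encoded by Klrb1c. Reads of Klrb1c are uncertain because of similar genes of its family, and this holds for each of its values. Unstimulated cells were taken at 0.5 h alone, so each comparison with them joins the stimulus with a longer time in culture. The labels name no sort or gate and do not say whether the replicates of a group are separate animals, so the p-values measure the spread between these libraries, which can be technical. The values were log2 normalized counts of 12000 genes. Group values are means ± SD of 3 libraries, log2 changes are given ± SE or alone, and a gene rose or fell where its adjusted p from limma, corrected by the Benjamini-Hochberg method, was under 0.05.

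Libraries of the same group resembled each other, with correlations from 0.934 to 0.977. The first principal component, with 38.4% of the variance, placed the unstimulated libraries between -67.6 and -64.9, those given anti-NK1.1 between -46.1 and -27.9, and those given IL-12 and IL-18 between 66.9 and 73.1. The anti-NK1.1 3 h group was the most spread, with a median SD of 0.450 per gene against 0.260 to 0.331 in the other groups, and its replicate 3 had the lowest array weight, 0.355. Relative depth, read from the spacing of the lowest values, ranged from 0.354 to 1.85 and was lowest at 3 h, in replicate 1 of IL-12 and IL-18 (0.354) and replicate 1 of anti-NK1.1 (0.361). Between 79 and 597 genes stood at 0 in a library, and 1577 genes did so in at least 1. The file also gave each library 1 of 2 unexplained values, MK1 or MK2. All libraries given IL-12 and IL-18 had MK1, all unstimulated and anti-NK1.1 6 h libraries had MK2, and anti-NK1.1 3 h replicates 1 and 2 had MK1 while replicate 3 had MK2. No value of MK thus occurs in both groups when IL-12 and IL-18 are compared with unstimulated cells or with anti-NK1.1 at 6 h, and a term for MK there rests on the anti-NK1.1 3 h libraries alone.

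**Figure D1:**
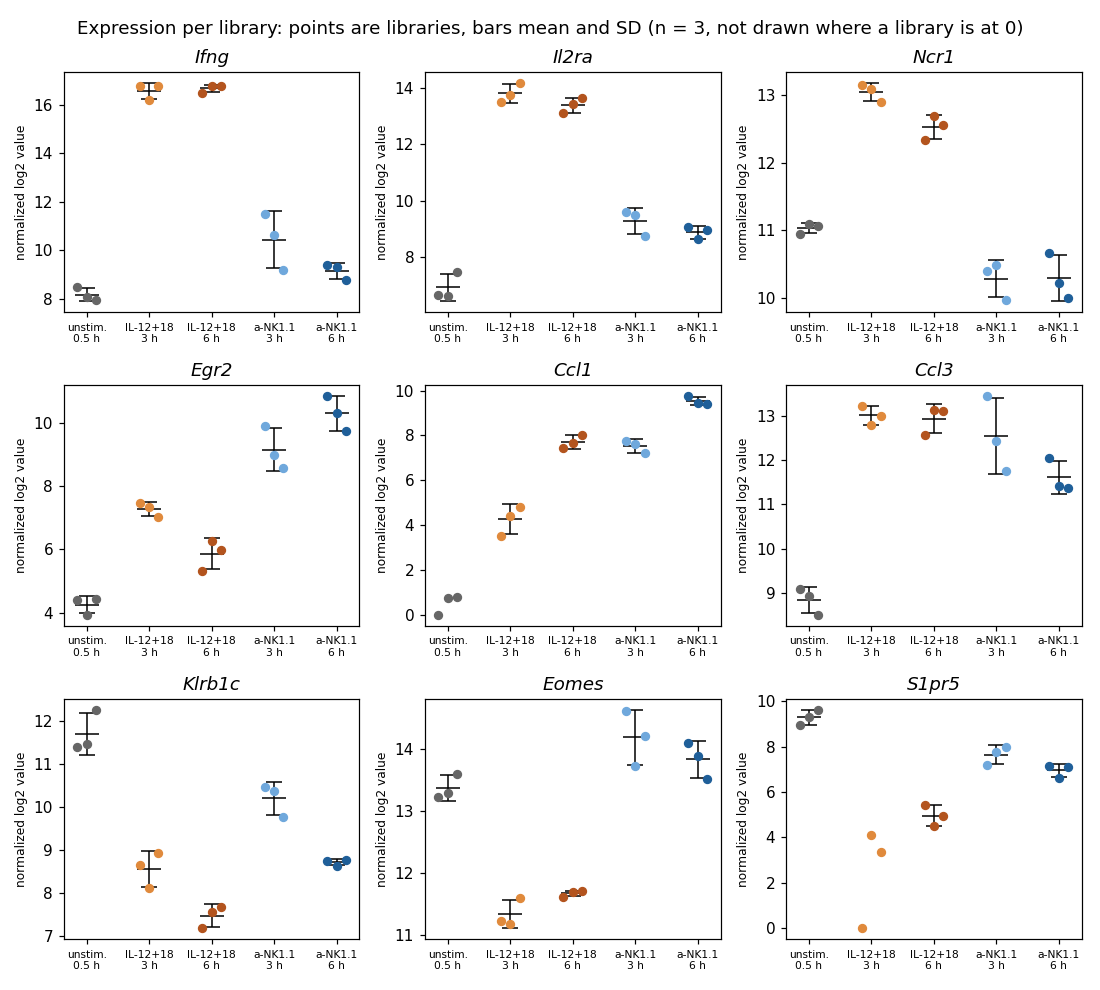
Log2 values of 9 genes (vertical axes) in the 5 groups (horizontal axes), with 1 point per library and bars for mean ± SD where no library is at 0. Ifng reached a mean of 16.58 with IL-12 and IL-18 at 3 h against 8.18 in unstimulated cells, while Egr2 was highest with anti-NK1.1 at 6 h (10.29).

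The comparison of IL-12 and IL-18 at 3 h with unstimulated cells asked what the cytokines change early. By the rule for naming genes, the largest rise was that of Ifng and the largest fall that of S1pr5. Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), which encodes interferon gamma, rose from 8.18 ± 0.26 to 16.58 ± 0.33, a log2 change of 8.40 ± 0.40 (adjusted p = 6.28e-11) or 339 times. It then stood near the top of the scale, where a further rise would show little. Csf2, which encodes the growth factor GM-CSF, had 1.54, 0 and 0.77 in the unstimulated libraries and rose to 8.73 ± 0.88. Il2ra, the alpha chain of the IL-2 receptor, rose by 6.90 ± 0.29 to 13.81 ± 0.35, and Zbtb32, a transcription factor that NK cells need to proliferate in viral infection, rose by 7.27 ± 0.50. Cxcl9 rose from 2.30, 2.92 and 0 in the unstimulated libraries to 9.80 ± 0.43, and Il22 from 0, 1.01 and 0 to 7.66 ± 0.22. The lipid transporter gene Mfsd2a rose by 6.83 ± 0.62, and Bhlhe22, a transcription factor gene, was listed at 0 in all 3 unstimulated libraries and averaged 7.73 ± 0.21 after 3 h. S1pr5, whose product lets NK cells follow sphingosine 1-phosphate out of tissue, fell from 9.30 ± 0.33 to 0, 4.11 and 3.36. Cnnm2 changed by -5.93, Dtx1, a Notch pathway ubiquitin ligase gene, by -5.27, the sulfate transporter gene Slc26a11 by -5.16, Qrfp by -5.08, Phactr3 by -4.53 and the retinal reductase gene Dhrs3 by -4.48, while Rap1gap2 fell from 8.19 ± 0.23 to 0, 4.11 and 3.51. Among receptors, Klrb1c changed by -3.14, Ncr1, which encodes NKp46, rose by 2.02 ± 0.23, and Il18r1 rose by 2.05 ± 0.27. The transcription factor gene Eomes had a log2 change of -2.03, and Irf4 and Myc of 2.70 and 3.18, while Tbx21 did not pass the test (0.34, adjusted p = 0.216). Gzmb and Nr4a1 did not pass it either (0.28 and 0.00).

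All 35 measured genes of ribosome biogenesis rose after 3 h of IL-12 and IL-18 (median log2 change 2.58, 35 and 0 adjusted over the list alone, camera adjusted p = 6.46e-21, and adjusted p = 0.000127 with an estimated correlation), among them Nop16 (4.75), Wdr12 (4.09) and Nolc1 (3.64). Of 25 genes of migration and tissue egress, 1 rose, 18 fell and 6 did not pass the test (1 and 18 adjusted over the list alone), with S1pr1 at -4.30 and S1pr4 at -3.25 (median -1.53, camera adjusted p = 3.42e-06, and adjusted p = 0.0157 with an estimated correlation). Among 14 chemokines, 9 rose, 2 fell and 3 did not pass the test (9 and 2 adjusted over the list alone), with a median of 2.64 (camera adjusted p = 0.0001, and adjusted p = 0.154 with an estimated correlation). Cxcl10 rose by 5.18, Ccl4 by 2.76 and Xcl1 by 3.18, and Ccl3, whose reads are uncertain because of near-identical copies, by 4.17. Secreted cytokines numbered 19, of which 12 rose, 3 fell and 4 did not pass the test (12 and 3 adjusted over the list alone), with Tnfsf14, the ligand LIGHT, at 4.40. The median was 1.29, with camera adjusted p = 0.00099 and adjusted p = 0.154 with an estimated correlation. The 30 NF-kB targets included Bcl2l1, which encodes the survival protein Bcl-xL (4.53), and 19 rose, 1 fell and 10 did not pass the test (21 and 1 adjusted over the list alone). A median of 1.14 gave camera adjusted p = 1.77e-06, and adjusted p = 0.154 with an estimated correlation. Of 22 STAT targets, 15 rose, 2 fell and 5 did not pass the test (15 and 2 adjusted over the list alone), with Gadd45g at 6.33, Pim2 at 4.46 and the feedback inhibitors Socs1 and Cish at 3.70 and 3.65. The median was 1.47, with camera adjusted p = 6.14e-07 and adjusted p = 0.154 with an estimated correlation. In the list of 24 genes of amino acid and polyamine metabolism, 17 rose, 2 fell and 5 did not pass the test (17 and 2 adjusted over the list alone), with the spermidine synthase gene Srm at 4.47 and the transporter gene Slc1a4 at 4.26. A median of 1.70 gave camera adjusted p = 1.66e-06, and adjusted p = 0.154 with an estimated correlation. Activating NK receptors and their adapters moved down, with 3 of 26 rising, 14 falling and 9 not passing the test (3 and 14 adjusted over the list alone); Cd2 and Cd27 stood at -3.79 and -3.78, against a rise of Crtam by 3.38. The median was -0.86, with camera adjusted p = 0.000886 and adjusted p = 0.154 with an estimated correlation. Inhibitory NK receptors also moved down, with 3 of 25 rising, 13 falling and 9 not passing the test (3 and 14 adjusted over the list alone), among them Klra10 (-2.71). A median of -0.86 gave camera adjusted p = 0.00299, and adjusted p = 0.154 with an estimated correlation. In each list called in any comparison, the median, the mean and the camera test had the same sign. The 26 cytokine receptors had a median of -0.83 (5 rose, 15 fell and 6 did not pass the test, 6 and 16 adjusted over the list alone, camera adjusted p = 0.334), with Il1rl1, the IL-33 receptor, at 3.86 and Il15ra at 2.76. The 13 innate lymphoid cell markers had a median of 0.88 (6 rose, 2 fell and 5 did not pass the test, 6 and 2 adjusted over the list alone, camera adjusted p = 0.0779), with Tnfrsf25 at 3.71. Of 4 B cell markers, 0 rose, 2 fell and 2 did not pass the test (0 and 2 adjusted over the list alone), and Cd22 was listed at 0 in all 3 libraries given the cytokines against 4.80 ± 0.55 in unstimulated cells. The median was -1.72, with camera adjusted p = 0.334. Tnf (0.94) and Prf1 (-1.11) passed with all libraries but not without IL-12 and IL-18 3 h replicate 2 (0.79 and -0.98), and Socs3 passed (1.98) but not with a term for MK (1.02). Of 5395 genes that changed, 2579 up and 2816 down, 2947 also passed in the same direction with that term, which rests on the anti-NK1.1 3 h libraries alone.

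After 6 h of IL-12 and IL-18, 5287 genes differed from unstimulated cells, 2711 up and 2576 down. Zbtb32 rose by 8.52 ± 0.50 (adjusted p = 3.63e-10) to 10.45 ± 0.17, Ifng by 8.51 ± 0.40 to 16.69 ± 0.15 and Il2ra by 6.48 ± 0.29 to 13.39 ± 0.27. Il22, Cxcl9 and Ccl1 reached 8.42 ± 0.19, 8.65 ± 0.09 and 7.70 ± 0.31, the last from 0, 0.74 and 0.77 in unstimulated cells. Cyp1b1, a cytochrome P450 gene, had 0, 0 and 1.20 in unstimulated cells and 7.72 ± 0.13 after 6 h, and Nqo1, which encodes a quinone reductase, rose from 0, 2.16 and 1.52 to 8.07 ± 0.08. Ly6a, uncertain because of similar family members, had a log2 change of 8.35. Fosb changed by -6.94, Itgad, the integrin alpha D gene, by -6.01, S1pr1 by -5.46, the cholesterol exporter gene Abcg1 by -5.25, Slc26a11 by -6.71, Dhrs3 by -5.75 and Phactr3 by -5.34, and Klrb1a, uncertain within its gene family, by -5.76. Klrb1c stood at 7.48 ± 0.26 against 11.70 ± 0.48 (log2 change -4.22 ± 0.28). Eomes changed by -1.70, Irf4 by 2.77, Myc by 2.95, Xcl1 by 3.23, Socs1 by 3.93, Cish by 3.10 and Tbx21 by 0.84, whereas Gzmb (0.41) and Il18r1 (0.40) did not pass the test. Ribosome biogenesis rose again, with 33 of 35 rising, 0 falling and 2 not passing the test (34 and 0 adjusted over the list alone), and Dkc1 and Nhp2 stood at 3.15 and 3.06. A median of 2.06 gave camera adjusted p = 2.67e-16, and adjusted p = 0.000387 with an estimated correlation. Migration genes were again lower, with 1 of 25 rising, 19 falling and 5 not passing the test (1 and 20 adjusted over the list alone), among them Itgam (-4.37) and S1pr5 (-4.34). The median was -1.74, with camera adjusted p = 1.63e-07 and adjusted p = 0.0065 with an estimated correlation. Immediate early genes, which cells switch on within minutes of a stimulus, moved down, with 6 of 29 rising, 19 falling and 4 not passing the test (6 and 19 adjusted over the list alone), and Nr4a2 and Klf4 stood at -4.82 and -3.23. A mean change of -0.99 gave camera adjusted p = 0.00345, and adjusted p = 0.292 with an estimated correlation. Of 31 genes of oxidative phosphorylation, 17 rose, 1 fell and 13 did not pass the test (18 and 1 adjusted over the list alone), and Cycs, the cytochrome c gene, stood at 2.04 but did not pass with a term for MK (1.75). The median was 0.74, with camera adjusted p = 0.000183 and adjusted p = 0.375 with an estimated correlation. Of 30 cytosolic ribosomal proteins, 10 rose, 0 fell and 20 did not pass the test (10 and 0 adjusted over the list alone). Their median was 0.47 (camera adjusted p = 0.0267, and adjusted p = 0.546 with an estimated correlation), and the call was lost with a term for MK (adjusted p = 0.77) and after removal of the GC and length trends (adjusted p = 0.404). It was also lost without unstimulated replicate 1 and without IL-12 and IL-18 6 h replicate 2 or 3 (adjusted p = 0.0502, 0.0523 and 0.0609). Genes of heat shock and dissociation stress numbered 15, and 9 rose, 0 fell and 6 did not pass the test (9 and 0 adjusted over the list alone), with the chaperone gene Hsph1 at 1.93. A median of 1.33 gave camera adjusted p = 0.00856, and adjusted p = 0.123 with an estimated correlation. Amino acid metabolism had 17 of 24 rising, 0 falling and 7 not passing the test (17 and 1 adjusted over the list alone, median 2.84, camera adjusted p = 3.24e-09), with Srm at 5.20. Camera also called chemokines (median 3.05), STAT targets (1.38), activating (-1.04) and inhibitory receptors (-0.99), and like amino acid metabolism each had an adjusted p = 0.123 with an estimated correlation. NF-kB targets (1.03) and secreted cytokines (0.58) were called too, with an adjusted p = 0.144 with an estimated correlation. The 15 immune checkpoints were not called (2 rose, 4 fell and 9 did not pass the test, 2 and 4 adjusted over the list alone, camera adjusted p = 0.515). Their median was 0.00 and their mean -0.44, with Cd200r1, the receptor gene for CD200, at -3.76. Of 27 genes of sterol and fatty acid synthesis, 10 rose, 5 fell and 12 did not pass the test (10 and 5 adjusted over the list alone, median 0.73, camera adjusted p = 0.418), with Scd2 at -4.77 and Lss at 2.31. Among 26 genes of mitosis, 5 rose, 4 fell and 17 did not pass the test (5 and 3 adjusted over the list alone), with the spindle motor genes Kif11 and Kif23 at -2.36 and 1.49. A median of 0.22 gave camera adjusted p = 0.96. With a term for MK, 2815 genes were called, 2360 of them the same, and Csf2 (5.47), Tnf (2.03), Cd69 (1.09) and Prf1 (-1.26) lost their calls (1.79, 1.57, 1.19 and -0.17), as did Ncr1, at 12.53 ± 0.18 against 11.03 ± 0.07. Egr2 (1.61) and Nr4a1 (-0.89) lost theirs too (0.74 and -1.09), and so did the lists of oxidative phosphorylation and secreted cytokines (adjusted p = 0.168 and 0.144).

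**Figure D2:**
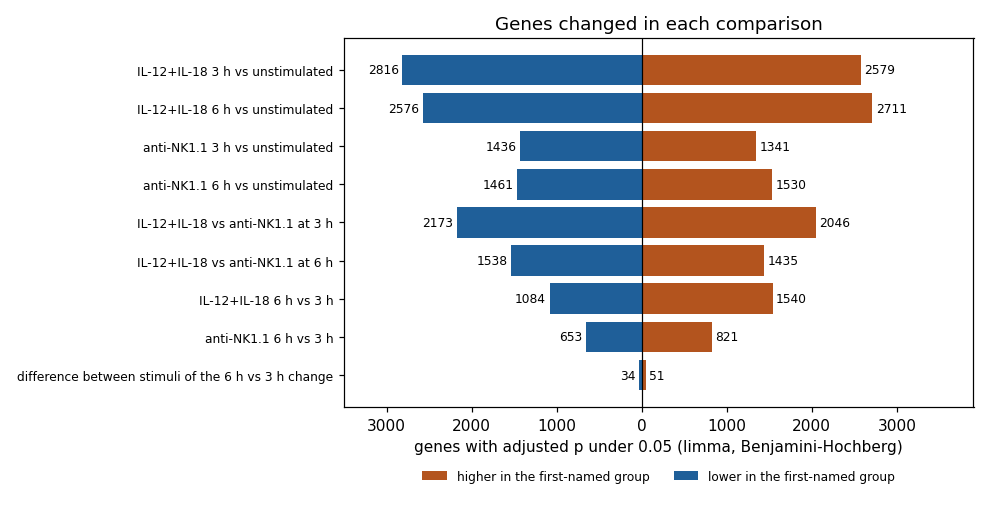
Bars give the number of genes with higher and lower values (horizontal axis, of 12000 genes) in each of the 9 comparisons (vertical axis). Counts ran from 5395 for IL-12 and IL-18 at 3 h against unstimulated cells to 85 for the difference between stimuli of the 6 h against 3 h change.

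The comparison of anti-NK1.1 at 3 h with unstimulated cells asked what ligation of a single activating receptor changes. Egr2, a transcription factor gene that antigen receptor and calcium signals switch on, rose from 4.25 ± 0.27 to 9.15 ± 0.69, a log2 change of 4.90 ± 0.34 (adjusted p = 5.2e-08), and its relative Egr3 rose by 2.87 ± 0.51. Ccl1 had 0, 0.74 and 0.77 in the unstimulated libraries and 7.53 ± 0.29 after 3 h, and Ccl4 rose by 3.66 ± 0.31 to 13.27 ± 0.64, beside 12.37 ± 0.26 with IL-12 and IL-18. Cxcl9 rose from 2.30, 2.92 and 0 to 8.98 ± 0.55, and Samd4, an RNA-binding protein gene, from 2.58, 0.74 and 0 to 7.97 ± 0.10. The adhesion molecule gene Amica1 rose by 3.77, the nucleolar protein gene Gpatch4 by 3.72, Crtam by 3.06 and Xcl1 by 2.86, and Ccl3 and Iigp1, both uncertain because of near-identical copies, by 3.70 and 5.68. Usp2 changed by -3.74, Fosb by -3.65, Cnnm4 by -3.05, the transcription regulator gene Hopx by -2.89, Gla, which encodes the lysosomal enzyme alpha-galactosidase, by -2.78, Trp53inp2 by -2.76 and Gramd3 by -2.75. Klrb1c itself fell from 11.70 ± 0.48 to 10.20 ± 0.38 (adjusted p = 0.00091). Il2ra changed by 2.37, Irf4 by 2.01, Socs1 by 1.59, Cish by 1.16 and Socs3 by -1.31. Ifng rose by 2.27 ± 0.40 (adjusted p = 0.000672) with 11.50, 10.64 and 9.19 in the 3 libraries, and within MK2, where replicate 3 stands alone against the unstimulated libraries, the change was 1.01. Prf1 (-1.49), Csf2 (3.00), Nr4a1 (0.83) and Eomes (0.82) passed the test but not within MK2 (-0.76, 0.55, 0.70 and 0.84). Gzmb (-1.16) lost its call without unstimulated replicate 2 (-1.07) and Ncr1 (-0.75) without anti-NK1.1 3 h replicate 3 (-0.59). Tnf (0.29), Cd69 (-0.37), Myc (-0.39) and Tbx21 (-0.22) did not pass the test. Chemokines had 8 of 14 rising, 2 falling and 4 not passing the test (8 and 2 adjusted over the list alone). The median was 2.67, with camera adjusted p = 6.12e-06 and adjusted p = 0.222 with an estimated correlation. In ribosome biogenesis, 19 rose, 0 fell and 16 did not pass the test (19 and 0 adjusted over the list alone), with Wdr12 at 2.22 and Polr1a at 1.67. A median of 0.80 gave camera adjusted p = 3.55e-07, and adjusted p = 0.0112 with an estimated correlation. Amino acid metabolism had 11 of 24 rising, 1 falling and 12 not passing the test (14 and 4 adjusted over the list alone), with Srm at 2.20 and Shmt1 at 2.19. The median was 1.00, with camera adjusted p = 0.000441 and adjusted p = 0.378 with an estimated correlation. Of 23 calcium and NFAT targets, 8 rose, 2 fell and 13 did not pass the test (8 and 3 adjusted over the list alone), with Egr3 among the rises. A median of 0.48 gave camera adjusted p = 0.033, and adjusted p = 0.443 with an estimated correlation. Cytotoxic effectors moved down, with 0 of 20 rising, 7 falling and 13 not passing the test (0 and 7 adjusted over the list alone), among them Nkg7 (-1.52), whose product is needed for granule release, and Serpinb9b (-0.99). The median was -0.58, with camera adjusted p = 0.0107 and adjusted p = 0.412 with an estimated correlation. Oxidative phosphorylation (0 rose, 4 fell and 27 did not pass the test, 0 and 3 adjusted over the list alone) and ribosomal proteins (0 rose, 4 fell and 26 did not pass the test, 0 and 3 adjusted over the list alone) were lower, with Sdhd at -1.63 and Rpsa at -1.28. The medians were -0.37 and -0.52, with camera adjusted p = 0.0036 and 0.00786 and adjusted p = 0.504 and 0.508 with an estimated correlation. Both calls were lost after removal of the GC and length trends (adjusted p = 0.0922 and 0.0626). Of 8 monocyte, macrophage and granulocyte markers, 0 rose, 5 fell and 3 did not pass the test (0 and 6 adjusted over the list alone), with Csf1r, the receptor for the macrophage growth factor, at -2.90 and the phagocyte oxidase gene Cybb at -1.75. The median was -1.51, with camera adjusted p = 0.000689 and adjusted p = 0.0357 with an estimated correlation. Dendritic cell markers had 1 of 13 rising, 8 falling and 4 not passing the test (1 and 8 adjusted over the list alone), with the class II gene H2-Eb1 at -1.34. A median of -0.95 gave camera adjusted p = 0.0107, and adjusted p = 0.227 with an estimated correlation. Of 7 erythroid and platelet markers, 3 rose, 0 fell and 4 did not pass the test (4 and 0 adjusted over the list alone), with the platelet integrin gene Itga2b at 0.90. The median was 0.73, with camera adjusted p = 0.0279 and adjusted p = 0.443 with an estimated correlation. The call for that list was lost without anti-NK1.1 3 h replicate 3 or unstimulated replicate 1 (adjusted p = 0.14 and 0.0551), as was that of Itga2b (0.72 and 0.79). Without anti-NK1.1 3 h replicate 3 the ribosomal protein list lost its call (adjusted p = 0.109), and without replicate 1 or unstimulated replicate 3 the calcium list did (adjusted p = 0.131 and 0.07). Of 2777 genes that changed, 1341 up and 1436 down, 1874 passed in the same direction within MK2, where anti-NK1.1 3 h is replicate 3 alone and the spread comes from the other groups, so that neither kept nor lost calls there decide much. The calcium and amino acid lists lost their calls in that fit (adjusted p = 0.247 and 0.117), and without unstimulated replicate 1 or 2 the counts were 1815 and 1777.

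After 6 h of anti-NK1.1, 2991 genes differed from unstimulated cells, 1530 up and 1461 down, and here all libraries compared had MK2. Egr2 reached 10.29 ± 0.54, a log2 change of 6.04 ± 0.34 (adjusted p = 1.19e-09), and Ccl1 and Cxcl9 reached 9.53 ± 0.18 and 9.19 ± 0.16. Slc17a6, known as a glutamate transporter gene of neurons, rose by 5.05 ± 0.41 to 7.95 ± 0.50, Capg, an actin-capping protein gene, by 4.86 ± 0.26, and Crtam by 4.54 ± 0.30. Irf4 rose by 3.72, Xcl1 by 2.85, Cish by 2.26, Socs1 by 1.81, Il2ra by 1.97, and Ly6a and Iigp1, both uncertain, by 5.36 and 5.37. Klrb1c changed by -2.98 to 8.72 ± 0.07, and Fosb changed by -5.37, Gramd3 by -3.86, Cnnm2 by -3.75, Clip4 by -3.56, Heatr9 by -3.54, Atp10d by -3.52, Tulp4 by -3.39 and the inhibitory Fc receptor gene Fcgr2b by -3.33. Prf1, the perforin gene, stood at 10.79 ± 0.11 against 13.02 ± 0.14 (log2 change -2.23 ± 0.35). Cd69 changed by -1.85, Socs3 by -2.51, Il18r1 by -1.17, Il12rb2 by -1.36 and Myc by -1.01. Ncr1 (-0.74) and Tbx21 (-0.72) passed the test but not without anti-NK1.1 6 h replicate 2 (-0.70 and -0.68). Ifng (0.99, adjusted p = 0.0795), Tnf (0.32), Gzmb (-0.08), Nr4a1 (-0.43) and Eomes (0.46) did not pass the test. In ribosome biogenesis, 18 rose, 0 fell and 17 did not pass the test (23 and 0 adjusted over the list alone), and this was the single list whose call held with an estimated correlation. A median of 0.95 gave camera adjusted p = 3e-07, and adjusted p = 0.0126 with an estimated correlation. Amino acid metabolism rose, with 18 of 24 rising, 1 falling and 5 not passing the test (18 and 2 adjusted over the list alone), including the serine and folate genes Phgdh (3.13) and Shmt2 (2.85). The median was 1.74, with camera adjusted p = 2e-07 and adjusted p = 0.158 with an estimated correlation. Of 14 chemokines, 9 rose, 2 fell and 3 did not pass the test (9 and 2 adjusted over the list alone), with Ccl22 at 5.41 and Cxcl2 at -3.25. A median of 2.20 gave camera adjusted p = 4.13e-05, and adjusted p = 0.158 with an estimated correlation. Immediate early genes had 2 of 29 rising, 14 falling and 13 not passing the test (2 and 17 adjusted over the list alone), with Fos at -3.18 and Fosl2 at -2.19, while Egr2 and Irf4 moved the other way. The median was -0.91, with camera adjusted p = 4.13e-05 and adjusted p = 0.164 with an estimated correlation. Of 40 NK transcription factors, 6 rose, 13 fell and 21 did not pass the test (6 and 14 adjusted over the list alone), with Bach2, a repressor that restrains lymphocyte activation, at 2.44 and Ahr at -2.29. A median of -0.41 gave camera adjusted p = 0.0204, and adjusted p = 0.316 with an estimated correlation. Activating (1 rose, 12 fell and 13 did not pass the test, 2 and 14 adjusted over the list alone) and inhibitory receptors (1 rose, 7 fell and 17 did not pass the test, 1 and 8 adjusted over the list alone) moved down, with the Fc receptor gene Fcgr3 at -1.62 and Klrg1 at -1.82. The medians were -0.66 and -0.32, with camera adjusted p = 0.00486 and 0.0141 and adjusted p = 0.164 and 0.203 with an estimated correlation. Migration genes had 2 of 25 rising, 9 falling and 14 not passing the test (2 and 11 adjusted over the list alone), with Klf2 at -2.16 and a rise of Itga1 by 2.92. A median of -0.48 gave camera adjusted p = 0.0117, and adjusted p = 0.158 with an estimated correlation. In 32 genes of DNA replication, 2 rose, 11 fell and 19 did not pass the test (2 and 12 adjusted over the list alone), with Mcm10 at -1.60 and Ccne2 at -1.65. The median was -0.30, with camera adjusted p = 0.0226 and adjusted p = 0.13 with an estimated correlation. Monocyte markers (0 rose, 5 fell and 3 did not pass the test, 0 and 6 adjusted over the list alone) and dendritic cell markers (0 rose, 5 fell and 8 did not pass the test, 1 and 5 adjusted over the list alone) were lower, with Csf1r at -2.65, Lyz2 at -2.17 and Cd209a at -3.93. The medians were -1.23 and -0.84, with camera adjusted p = 0.00132 and 0.0146 and adjusted p = 0.0514 and 0.158 with an estimated correlation. Cytotoxic effectors (1 rose, 6 fell and 13 did not pass the test, 1 and 6 adjusted over the list alone) and oxidative phosphorylation (4 rose, 1 fell and 26 did not pass the test, 3 and 1 adjusted over the list alone) were called in opposite directions. The medians were -0.30 and 0.43, with camera adjusted p = 0.0274 and 0.0229 and adjusted p = 0.532 and 0.681 with an estimated correlation. Without 1 library the cytotoxic call was lost for anti-NK1.1 6 h replicate 3 and unstimulated replicates 1 and 2 (adjusted p = 0.109, 0.0579 and 0.0572), that of oxidative phosphorylation for anti-NK1.1 6 h replicates 1 and 2 (adjusted p = 0.125 and 0.0561), and that of DNA replication for replicate 1 (adjusted p = 0.0523). The oxidative phosphorylation call was also lost after removal of the GC and length trends (adjusted p = 0.0563), and that of DNA replication among genes with a mean log2 value of at least 5 (adjusted p = 0.104).

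**Figure D3:**
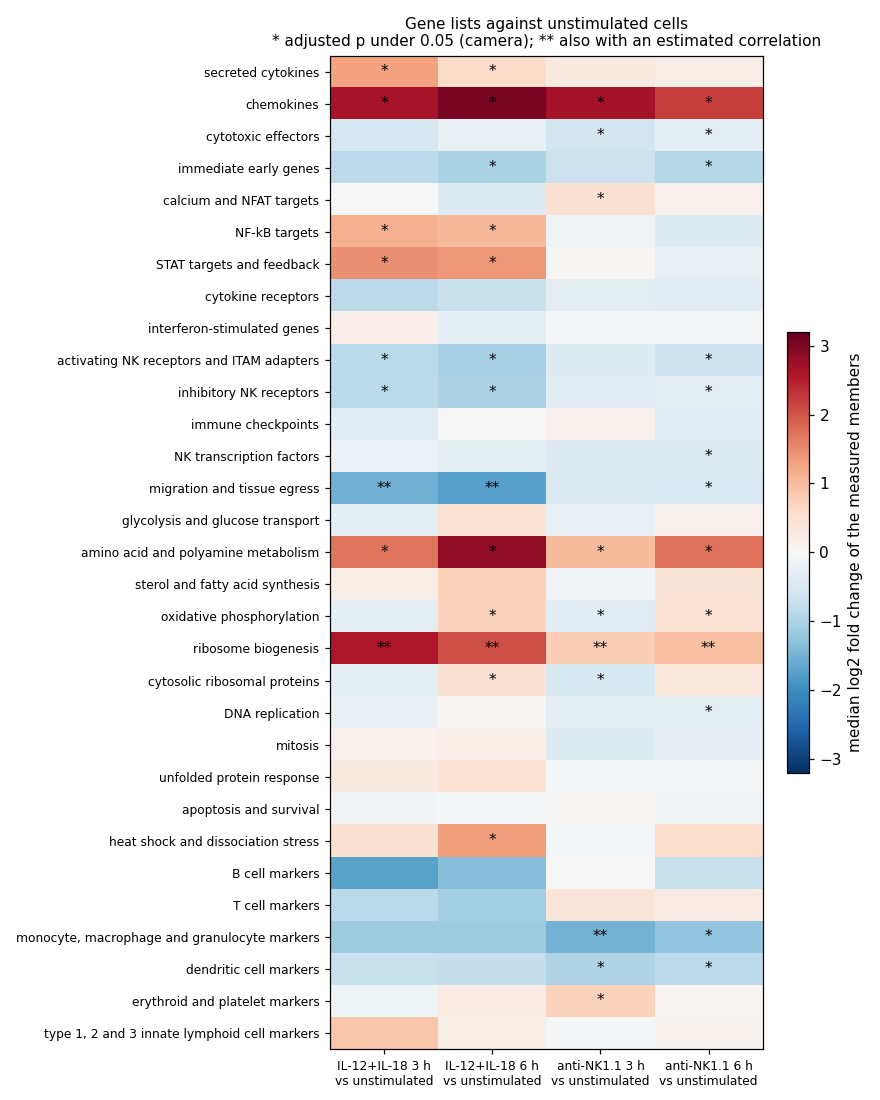
Heat map of the median log2 change of each of 31 gene lists (vertical axis) in the 4 comparisons with unstimulated cells (horizontal axis), with 1 star for a camera call and 2 where the call held with an estimated correlation. Ribosome biogenesis had medians of 2.58, 2.06, 0.80 and 0.95.

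Changes with both stimuli against the same unstimulated cells were correlated, with r = 0.534 at 3 h and 0.647 at 6 h. Simulations with no response gave 0.500 from shared controls, which is no baseline for r. Covariance was 0.101 against 0.690 and 0.883 in the data. At 3 h, 840 genes were higher and 915 lower with both stimuli, against 288 and 337 if the calls were independent, and 118 had opposite signs. At 6 h the counts were 1121 and 1020, against 346 and 314, with 128 opposite. The 3 controls were not divided by stimulus, as 1 side would keep 1 library. Part of the overlap may come from them or time in culture. Crtam and Wdr12 rose with both stimuli at 3 h, by 3.38 and 4.09 with IL-12 and IL-18 and by 3.06 and 2.22 with anti-NK1.1. Cxcl9, Ccl1 and Xcl1 rose, and Klrb1c and Fosb fell, with both at 6 h. With IL-12 and IL-18, 3624 genes were called at both times and 3598 had the same sign, and with anti-NK1.1 1515 were called at both times and 1506 had the same sign.

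At 3 h IL-12 and IL-18 were compared directly with anti-NK1.1, and 4219 genes differed, 2046 higher and 2173 lower with the cytokines. Ifng was higher by 6.14 ± 0.40 (adjusted p = 4.54e-09), and by 5.51 within MK1, where anti-NK1.1 replicates 1 and 2 remain. Zbtb32 was higher by 6.59 ± 0.50, Gadd45g, a stress and p38 pathway gene, by 6.20 ± 0.43, Mfsd2a by 5.86, Vash1 by 5.07, Pim2 by 4.97, Csf2 by 4.95, Il2ra by 4.53 and Batf, a transcription factor gene of activated lymphocytes, by 4.76. Il22 had 0, 0.84 and 0 with anti-NK1.1 against 7.66 ± 0.22, and Bhlhe22 had 3.51, 0 and 0 against 7.73 ± 0.21. Lower with IL-12 and IL-18 were Qrfp (-5.56), Slc26a11 (-5.41), Tm6sf1 (-4.76), Egr3 (-4.13), Nlrc3 (-3.88), S1pr1 (-3.79), Egr2 (-1.89), Eomes (-2.85) and Klrb1c (-1.64), and S1pr5, which had 0, 4.11 and 3.36 against 7.65 ± 0.41. Ncr1 (2.77), Gzmb (1.43), Cd69 (2.10), Myc (3.57), Socs1 (2.11), Socs3 (3.29), Cish (2.48) and Il18r1 (1.86) were higher. Xcl1 (0.32), Tnf (0.65) and Prf1 (0.37) did not pass the test. Of STAT targets, 16 were higher, 2 lower and 4 did not pass the test (17 and 2 adjusted over the list alone), with Furin at 3.79. A median of 1.67 gave camera adjusted p = 3.48e-09, and adjusted p = 0.0988 with an estimated correlation. NF-kB targets had 17 of 30 higher, 1 lower and 12 not passing the test (17 and 1 adjusted over the list alone), with Bcl2l1, Nfkbiz and Icam1 at 3.68, 3.52 and 3.07. The median was 1.01, with camera adjusted p = 2.01e-08 and adjusted p = 0.0988 with an estimated correlation. Ribosome biogenesis had 31 of 35 higher, 0 lower and 4 not passing the test (33 and 0 adjusted over the list alone) and migration 1 of 25 higher, 18 lower and 6 not passing the test (2 and 18 adjusted over the list alone). The medians were 1.86 and -1.12, with camera adjusted p = 1.46e-17 and 3.29e-06 and adjusted p = 0.000278 and 0.0146 with an estimated correlation. Secreted cytokines had 11 of 19 higher, 3 lower and 5 not passing the test (12 and 4 adjusted over the list alone), and activating receptors 4 of 26 higher, 15 lower and 7 not passing the test (4 and 17 adjusted over the list alone), with Cd27 at -3.76. The medians were 1.45 and -0.90, with camera adjusted p = 0.00289 and 0.00129 and adjusted p = 0.125 and 0.152 with an estimated correlation. Heat shock genes (7 were higher, 0 lower and 8 did not pass the test, 7 and 0 adjusted over the list alone) and amino acid genes (12 were higher, 0 lower and 12 did not pass the test, 14 and 1 adjusted over the list alone) were higher, with Stip1 at 2.21 and Slc7a11 at 2.62. The medians were 0.75 and 1.01, with camera adjusted p = 0.0131 and 0.000141 and adjusted p = 0.152 and 0.275 with an estimated correlation. Among 26 genes of apoptosis and survival, 7 were higher, 5 lower and 14 did not pass the test (7 and 5 adjusted over the list alone), with the death receptor genes Fas and Tnfrsf10b at 3.29 and 2.80 and Bad at -1.72. The median was 0.12, with camera adjusted p = 0.486. Of 9 T cell markers, 1 was higher, 6 lower and 2 did not pass the test (1 and 6 adjusted over the list alone), with Cd28 at -2.96 and Themis at 3.49. A median of -1.22 gave camera adjusted p = 0.0325, and adjusted p = 0.125 with an estimated correlation. Inhibitory receptors (4 were higher, 11 lower and 10 did not pass the test, 4 and 13 adjusted over the list alone) and erythroid markers (0 were higher, 4 lower and 3 did not pass the test, 0 and 5 adjusted over the list alone) were lower, with Cd96 at -2.35 and Car2 at -1.53. The mean changes were -0.59 and -0.71, with camera adjusted p = 0.022 and 0.0439 and adjusted p = 0.275 and 0.539 with an estimated correlation. Within MK1, which leaves out anti-NK1.1 3 h replicate 3, 3456 of the genes were called again, and the T cell and erythroid lists were not (adjusted p = 0.0799 and 0.226). The inhibitory receptor call was lost without IL-12 and IL-18 3 h replicate 1 (adjusted p = 0.0549) and the erythroid call without replicate 2 or 3 (adjusted p = 0.105 and 0.0687).

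At 6 h 2973 genes differed between the stimuli, 1435 higher and 1538 lower with IL-12 and IL-18. Ifng was higher by 7.52 ± 0.40 (adjusted p = 3.49e-10), Zbtb32 by 6.93 ± 0.50, Gadd45g by 6.66 ± 0.43 and Tnfrsf8, which encodes the TNF receptor family member CD30, by 6.13 ± 0.43. Vash1 had 0, 2.30 and 1.01 with anti-NK1.1 and 9.48 ± 0.34 with the cytokines, Shisa2 had 0, 0 and 0.13 against 7.75 ± 0.21, and Il22 1.52, 1.58 and 0 against 8.42 ± 0.19. Cyp1b1 was higher with the cytokines by 7.12 ± 0.76. Itgad differed by -6.01, the integrin gene Itgax by -5.15, Slc26a11 by -5.96, Dhrs3 by -4.76, Cited4 by -4.67, Phactr3 by -4.60, Sorl1 by -4.44 and Egr2 by -4.43. Klrg1, an inhibitory receptor gene of mature NK cells, stood at 10.68 ± 0.05 with the cytokines against 6.53 ± 0.23 with anti-NK1.1 (log2 change 4.15 ± 0.20). Il2ra (4.51), Cd69 (2.94), Ncr1 (2.23), Myc (3.97), Socs3 (3.24), Tbx21 (1.56) and Il18r1 (1.58) were higher, and Eomes (-2.16) and Klrb1c (-1.24) lower. Gzmb (0.49), Xcl1 (0.38), Nr4a1 (-0.46) and Il12rb2 (0.46) did not pass the test. Ribosome biogenesis (30 were higher, 0 lower and 5 did not pass the test, 30 and 0 adjusted over the list alone) and migration (0 were higher, 13 lower and 12 did not pass the test, 2 and 16 adjusted over the list alone) differed as at 3 h, with S1pr1 at -3.71 and Ccr2 at -2.99. The medians were 1.26 and -1.12, with camera adjusted p = 8.13e-14 and 7.99e-07 and adjusted p = 0.000794 and 0.0102 with an estimated correlation. Of 9 T cell markers, 1 was higher, 7 lower and 1 did not pass the test (1 and 7 adjusted over the list alone), with Cd28 at -2.94. The median was -1.41, with camera adjusted p = 0.000446 and adjusted p = 0.0256 with an estimated correlation. STAT targets had 15 of 22 higher, 2 lower and 5 not passing the test (16 and 2 adjusted over the list alone), with Pim2 at 5.75 and Furin at 5.29. NF-kB targets had 18 of 30 higher, 0 lower and 12 not passing the test (19 and 0 adjusted over the list alone), with Nfkbie at 3.79 and Icam1 at 3.76. Secreted cytokines had 10 of 19 higher, 3 lower and 6 not passing the test (10 and 4 adjusted over the list alone), with Tnfsf11, the ligand RANKL, at -3.94. The medians of these 3 lists were 1.76, 1.43 and 1.71 (camera adjusted p = 2.43e-10, 3.94e-09 and 0.000446), and each had adjusted p = 0.056 with an estimated correlation. DNA replication (7 were higher, 1 lower and 24 did not pass the test, 9 and 1 adjusted over the list alone) was higher, with Ccnd2 at 2.25. A median of 0.60 gave camera adjusted p = 0.0209, and adjusted p = 0.056 with an estimated correlation. Of 25 genes of the unfolded protein response, 6 were higher, 2 lower and 17 did not pass the test (10 and 2 adjusted over the list alone), with Ppp1r15a at 1.42 and Dnajb9 at 1.20. The median was 0.60, with camera adjusted p = 0.0209 and adjusted p = 0.0637 with an estimated correlation. Amino acid metabolism had 11 of 24 higher, 0 lower and 13 not passing the test (12 and 0 adjusted over the list alone), with Srm at 2.37. Heat shock genes had 4 of 15 higher, 0 lower and 11 not passing the test (7 and 0 adjusted over the list alone), and oxidative phosphorylation 4 of 31 higher, 0 lower and 27 not passing the test (4 and 0 adjusted over the list alone). The medians of these 3 lists were 0.92, 0.66 and 0.40, with camera adjusted p = 6.27e-05, 0.0222 and 0.00788 and adjusted p = 0.199, 0.174 and 0.575 with an estimated correlation. Activating receptors (3 were higher, 12 lower and 11 did not pass the test, 4 and 17 adjusted over the list alone) and inhibitory receptors (4 were higher, 13 lower and 8 did not pass the test, 4 and 14 adjusted over the list alone) were lower, with Klrd1 at -2.47. The medians were -0.84 and -0.94, with camera adjusted p = 0.000446 and 0.00615 and adjusted p = 0.0956 and 0.174 with an estimated correlation. With a term for MK 1074 of the genes and 7 lists were called, and Csf2 (3.77), Tnf (1.71), Socs1 (2.12) and the uncertain Ccl3 (1.33) were not (0.08, 1.25, 1.29 and 0.14). The lists that lost their call with it were T cell markers (adjusted p = 0.0669), DNA replication (0.108), inhibitory receptors (0.138), heat shock (0.243), amino acid metabolism (0.417) and oxidative phosphorylation (0.909). DNA replication lost its call without anti-NK1.1 6 h replicate 1 (adjusted p = 0.0551), oxidative phosphorylation without replicate 3 (adjusted p = 0.117) and heat shock without IL-12 and IL-18 6 h replicate 3 (adjusted p = 0.0681). Removal of the GC and length trends also ended the oxidative phosphorylation call (adjusted p = 0.224), and a mean log2 value of at least 5 that of DNA replication (adjusted p = 0.069).

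Between 3 h and 6 h of IL-12 and IL-18, in libraries that all had MK1, 2624 genes changed, 1540 up and 1084 down, a balance that was 1359 and 1224 with median-of-ratios rescaling and 1082 and 963 after removal of the GC and length trends. Ifng (0.10), Il2ra (-0.41), Xcl1 (0.05), Gzmb (0.14), Irf4 (0.07) and Myc (-0.23) did not pass the test, with Ifng near the top of the scale at both times. Scand1 rose by 4.25 ± 0.41 (adjusted p = 1.1e-05), Cyp1b1 by 4.22 ± 0.76, Ccl1 by 3.45 ± 0.34, Zcchc24 by 3.10 ± 0.41 and the septin gene Sept9 by 3.02 ± 0.26. Amph changed by -4.09, Zbtb10 by -3.42, the kinase gene Pak1 by -3.28, Utrn, which encodes the cytoskeletal protein utrophin, by -3.24 and Bhlhe22 by -3.06. Egr2 (-1.40), Socs3 (-1.25) and Il18r1 (-1.64) also fell. Of 31 genes of oxidative phosphorylation, 20 rose, 0 fell and 11 did not pass the test (24 and 0 adjusted over the list alone), and of 30 ribosomal proteins, 16 rose, 0 fell and 14 did not pass the test (18 and 0 adjusted over the list alone). The medians were 0.82 and 0.90, with camera adjusted p = 1.91e-09 and 5.83e-06 and adjusted p = 0.375 and 0.483 with an estimated correlation. In glycolysis and glucose transport, with 24 genes measured, 12 rose, 1 fell and 11 did not pass the test (12 and 1 adjusted over the list alone). The median was 0.49, with camera adjusted p = 0.00323 and adjusted p = 0.317 with an estimated correlation. Interferon-stimulated genes moved down, with 2 of 41 rising, 9 falling and 30 not passing the test (2 and 9 adjusted over the list alone). A median of -0.46 gave camera adjusted p = 0.00447, and adjusted p = 0.194 with an estimated correlation. Amino acid metabolism had 9 of 24 rising, 0 falling and 15 not passing the test (12 and 0 adjusted over the list alone). Ribosome biogenesis moved down, with 4 of 35 rising, 9 falling and 22 not passing the test (4 and 10 adjusted over the list alone). Immediate early genes had 2 of 29 rising, 11 falling and 16 not passing the test (3 and 11 adjusted over the list alone), a call lost without IL-12 and IL-18 6 h replicate 1 (adjusted p = 0.081). The medians of these 3 lists were 0.69, -0.50 and -0.34, with camera adjusted p = 0.0105, 0.00736 and 0.011 and adjusted p = 0.558, 0.209 and 0.524 with an estimated correlation. Without IL-12 and IL-18 3 h replicate 2 the count of genes was 1485, without 6 h replicate 2 it was 1256 and without 6 h replicate 3 it was 1570, and without 3 h replicate 3 Klrb1c, at -1.08 with all libraries, lost its call (-0.90).

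Between 3 h and 6 h of anti-NK1.1, 1474 genes changed, 821 up and 653 down, in libraries of both MK values. The balance turned with median-of-ratios rescaling (729 up and 739 down) and after removal of the GC and length trends (580 up and 604 down). Slc17a6 rose by 3.26 ± 0.41 (adjusted p = 0.000285), Adam8, a metalloprotease gene of leukocytes, by 2.90 ± 0.32, Wnt10b by 2.84 ± 0.55, Capg by 2.75 ± 0.26 and the phosphatase gene Ptpn5 by 2.40 ± 0.33. Heatr9 changed by -2.72, Pip5k1b by -2.63, the cholesterol exporter gene Abca1 by -2.51, Fos by -2.37 and Rad18 by -2.31. Irf4 rose by 1.71. Cd69 changed by -1.48, Nr4a1 by -1.26 and Il18r1 by -1.36, and Xcl1 (-0.01), Tnf (0.04) and Il2ra (-0.40) did not pass the test. Oxidative phosphorylation had 15 of 31 rising, 0 falling and 16 not passing the test (23 and 0 adjusted over the list alone). Ribosomal proteins had 12 of 30 rising, 0 falling and 18 not passing the test (22 and 0 adjusted over the list alone), and amino acid metabolism 7 of 24 rising, 0 falling and 17 not passing the test (9 and 1 adjusted over the list alone). Their medians were 0.77, 0.88 and 0.58 (camera adjusted p = 8.91e-11, 1.48e-07 and 0.00071), and each had adjusted p = 0.459 with an estimated correlation. Glycolysis was called up, with 9 of 24 rising, 0 falling and 15 not passing the test (9 and 0 adjusted over the list alone). Secreted cytokines (0 rose, 6 fell and 13 did not pass the test, 0 and 6 adjusted over the list alone) and immediate early genes (3 rose, 8 fell and 18 did not pass the test, 3 and 12 adjusted over the list alone) were called down. The medians of these 3 lists were 0.35, -0.47 and -0.25, with camera adjusted p = 0.0447, 0.00966 and 0.00321, and each had adjusted p = 0.459 with an estimated correlation. The glycolysis, cytokine and immediate early calls were lost without anti-NK1.1 3 h replicate 1 (adjusted p = 0.0828, 0.082 and 0.082), the first also without anti-NK1.1 3 h replicate 2 or 6 h replicate 2 (adjusted p = 0.124 and 0.101) and the cytokine call without 3 h replicate 2 (adjusted p = 0.0578). The glycolysis call was lost too with the replicate block, in the fit to the groups compared alone and with no mean-variance trend (adjusted p = 0.0592, 0.0576 and 0.0638). Within MK2, where anti-NK1.1 3 h is replicate 3 alone and the spread comes from the other groups, all 3 were lost (adjusted p = 0.41, 0.836 and 0.0941). In that fit, which rests on 1 library at 3 h, 1123 of the genes were called again, and Ifng (-1.28), Klrb1c (-1.48) and Socs3 (-1.20) were not (-0.02, -1.05 and -0.55), while the counts without anti-NK1.1 3 h replicate 3 and 6 h replicates 1 and 2 were 633, 507 and 650.

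The changes between 3 h and 6 h had a correlation of 0.489 between the stimuli, with 484 genes higher and 270 lower in both, against 105 and 59.0 if the calls were independent, and 20 with opposite signs. The test of a difference between the stimuli called 85 genes, 51 higher and 34 lower with IL-12 and IL-18, a balance that turned with a term for MK (111 and 128). Dapk2, a death-associated kinase gene, changed by 2.19 with the cytokines and by -0.85 with anti-NK1.1, a difference of 3.04 ± 0.33 (adjusted p = 0.000347). Asb2, which encodes a ubiquitin ligase subunit, changed by 2.16 and -0.37 (difference 2.53 ± 0.30), and the glutathione transferase gene Gstm1 by 2.03 and -0.57 (difference 2.60 ± 0.36). Inpp4b, a phosphoinositide phosphatase gene, changed by -0.57 and 2.00 (difference -2.57 ± 0.37) and Slc17a6 by -0.03 and 3.26 (difference -3.29 ± 0.58). Egr2 changed by -1.40 and 1.14 (difference -2.54 ± 0.48, adjusted p = 0.0185), a call lost without anti-NK1.1 6 h replicate 1 (-2.27), and Itgad by -2.86 and 0.90 (difference -3.76 ± 0.70), lost without IL-12 and IL-18 6 h replicate 2 (-3.62). Ifng (1.38), Xcl1 (0.06), Il2ra (-0.02), Gzmb (-0.94) and Klrb1c (0.40) did not pass the test. Of the 31 lists, camera called ribosome biogenesis, of which 0 were higher, 0 lower and 35 did not pass the test (0 and 4 adjusted over the list alone), while 0 were higher and 8 lower at an unadjusted limma p under 0.05. Its median difference was -0.56, from -0.50 with IL-12 and IL-18 and 0.11 with anti-NK1.1 (camera adjusted p = 0.000422, and adjusted p = 0.0757 with an estimated correlation). Without IL-12 and IL-18 3 h replicate 2 the count was 56, without 6 h replicates 2 and 3 it was 26 and 51, without anti-NK1.1 6 h replicates 1, 2 and 3 it was 43, 47 and 54, and without anti-NK1.1 3 h replicate 2 it was 141.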

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

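The tests of r for GC, length, depth and gene span and the exchanges of libraries between groups were set before their results were seen. The other tests of explanations, the share of r kept among them, were chosen only after the result was seen. The change from 3 h to 6 h differed between the stimuli for 85 genes. Lgals9, which encodes galectin-9, changed by 1.60 with IL-12 and IL-18 and by -1.50 with anti-NK1.1 (difference 3.10 ± 0.64, adjusted p = 0.0265). For Dapk2 the changes were 2.19 and -0.85 (3.04 ± 0.33, adjusted p = 0.000347). Gstm1 moved by 2.03 and -0.57 (2.60 ± 0.36, adjusted p = 0.0023). Il12rb1, a chain of the IL-12 receptor, moved by 2.95 and 0.40 (2.55 ± 0.52, adjusted p = 0.0258). Asb2 went up by 2.16 against -0.37 (2.53 ± 0.30, adjusted p = 0.00069). In the other direction, the difference was -1.65 ± 0.33 for Cish (adjusted p = 0.0233), which rose with anti-NK1.1 and did not pass the test with IL-12 and IL-18. The values of Egr2 were -1.40 and 1.14 (-2.54 ± 0.48, adjusted p = 0.0185). Inpp4b had -0.57 and 2.00 (-2.57 ± 0.37, adjusted p = 0.00257). Zbtb41, a zinc finger gene, had -1.36 and 1.37 (-2.73 ± 0.58, adjusted p = 0.033). With Slc17a6 the changes were -0.03 and 3.26 (-3.29 ± 0.58, adjusted p = 0.0115). Itgad had -2.86 and 0.90 (-3.76 ± 0.70, adjusted p = 0.0185). Lgals9, Il12rb1, Zbtb41, Cish, Egr2 and Itgad each lost the call in at least 1 fit that left out a library.

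The libraries were also put into other groups of the same sizes. Of 100 groupings, drawn at random from those possible and with the real one among them, 7 gave the difference between stimuli at least 85 genes, and the highest other count was 2036, so chance is not excluded by this count. The 6 others exchanged at least 2 more libraries between the stimuli at 1 time than at the other and so carried the difference between stimuli into the test, and the rest of those drawn gave at most 11 genes with a median of 0. In each of the other 8 comparisons the real grouping was 1 of 10, which is too few groupings for a share under 0.05. The highest other count was 0 against 5395, 5287, 2777, 2991, 2973 and 2624 genes, 1 against 4219 for the stimuli at 3 h, and 5 against 1474 for anti-NK1.1 at 6 h and 3 h.

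Genes moved in the same direction from 3 h to 6 h with both stimuli (r = 0.489), although these groups share no library. Differences in depth between the 3 h and 6 h libraries might have caused this, but among 3158 genes with a mean log2 value of at least 9, where zeros and steps matter least, r was 0.647 with a jackknife spread of 0.111, which argues against that explanation. After removal of the trends with GC content and transcript length r was 0.446 (spread 0.0873), and with that spread it reaches below the limit set beforehand for arguing against these trends, so a part played by them stays open. As the whole cause they are argued against, because 91.3% of r (spread 4.17) was kept after their removal. Without the gene span trend r was 0.458 (spread 0.0838). This argues against reads of long genes at 3 h as the whole cause. A partial role stays open. The shortest and longest genes had medians of 0.42 and -0.20 with IL-12 and IL-18 and 0.32 and -0.17 with anti-NK1.1. Time in culture and the response common to both stimuli were not tested, because no unstimulated cells were taken at 3 h or 6 h.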

How the results depend on the processing

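Counts of genes, calls of lists and values of named genes were fitted again with 1 choice changed, and the tests with a term for MK, within 1 value of MK, with array weights, rescaling, GC and length, no trend and a mean log2 value of at least 5 were chosen only after the results were seen. Alternatives made for counts and chosen beforehand (other size factors, a Wald test, voom and count filters) were not run, because the values are not counts. The correlations between changes were not computed again without a trend, within 1 value of MK or in the groups compared alone, and the counts of genes shared by comparisons and the values of the tests of explanations were not computed again in any setting.

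Gene counts moved by more than 1.5 times in these settings. A fit to the groups compared alone gave 297 genes for anti-NK1.1 at 6 h and 3 h and 37 for the difference between stimuli. A limit of 1 on the absolute log2 change gave 1684 for IL-12 and IL-18 at 6 h and 3 h and 966 for anti-NK1.1, and array weights gave 764 for the latter. With a term for MK the counts were 2815 for IL-12 and IL-18 at 6 h against unstimulated cells, 1528 for the stimuli at 6 h, 2293 for anti-NK1.1 at 6 h and 3 h and 239 for the difference, and within MK2, with 1 library at 3 h, the anti-NK1.1 count over time was 2436. Rescaling turned the balance of rises and falls for anti-NK1.1 at 3 h (1400 up and 1389 down) and 6 h (1467 and 1525), and the term for MK for IL-12 and IL-18 at 6 h (1371 and 1444). For the difference it turned with that term (111 and 128), in the groups alone (16 and 21) and without anti-NK1.1 6 h replicate 1 (21 and 22). A block for the replicate number gave 5407, 5323, 2800, 3013, 4205, 2977, 2619, 1491 and 88 genes in the order of the comparisons. For 894 results of named genes the term for MK weakened 142 past the threshold and reversed the sign of 6, rescaling weakened 3, the block 5, and leaving out a library 392 of 5550.

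With 1 library left out, counts ran from 4586 to 4927 and 4467 to 4751 for IL-12 and IL-18 at 3 h and 6 h against unstimulated cells, and from 1777 to 2725 and 2211 to 2467 for anti-NK1.1. Those of the stimuli ran from 3578 to 4051 at 3 h and 2208 to 2536 at 6 h. Over time they ran from 1256 to 2479 with IL-12 and IL-18 and from 507 to 1654 with anti-NK1.1, and for the difference from 26 to 141. The lowest counts came without unstimulated replicate 2 (1777), IL-12 and IL-18 6 h replicate 2 (1256 and 26) and anti-NK1.1 6 h replicate 1 (507), and the cause was not tested. The correlation of the stimuli ran from 0.488 to 0.559 at 3 h and 0.627 to 0.660 at 6 h, and that of their changes over time from 0.425 to 0.513.

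The sign turned for Il12rb2 at 3 h of IL-12 and IL-18 (0.74 with a term for MK) and for Tigit (0.79), Rpl8 (-0.0075) and Socs3 (-0.23) at 6 h. Manf in the comparison of stimuli at 6 h became -0.44 with that term, and Pycr1 at 3 h of anti-NK1.1 became -0.25 with it and -0.25 within MK2. Cytosolic ribosomal proteins at 6 h of IL-12 and IL-18 turned with it too (adjusted p = 0.770), and cytokine receptors were called by fry in the opposite direction for the stimuli at 3 h (adjusted p = 0.0116).

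Called lists numbered 9, 13, 10, 13, 11, 13, 7, 6 and 1 in the order of the comparisons, and 2, 2, 2, 1, 2, 3, 0, 0 and 0 with an estimated correlation. The calls that held with it were ribosome biogenesis in all 4 comparisons with unstimulated cells and both of the stimuli, migration in both of IL-12 and IL-18 with unstimulated cells and both of the stimuli, monocyte markers at 3 h of anti-NK1.1 and T cell markers for the stimuli at 6 h. With fry the counts moved to 22, 24 and 18 for the first 3 comparisons, 19 for the stimuli at 3 h, 13 for IL-12 and IL-18 over time and 2 for the difference. The term for MK left 7 lists for the stimuli at 6 h, T cell markers not among them (adjusted p = 0.0669), and 2 for the difference, and removal of the GC and length trends gave 11 for anti-NK1.1 over time. Further calls of lists were lost. Among genes with a mean log2 value of at least 5 these were secreted cytokines at 3 h and 6 h of IL-12 and IL-18 (adjusted p = 0.078 and 0.164), calcium targets, dendritic and erythroid markers at 3 h of anti-NK1.1 (0.0517, 0.0517 and 0.0517) and dendritic markers at 6 h (0.0541). The fit to the groups alone ended calcium targets at 3 h of anti-NK1.1 (0.058), array weights the erythroid list there and for the stimuli at 3 h (0.0568 and 0.0973), no trend the latter (0.0542), and the term for MK 3 lists of anti-NK1.1 over time (glycolysis 0.374, cytokines 0.813 and immediate early genes 0.135), calcium and amino acid lists at 3 h of anti-NK1.1 (0.215 and 0.116) and T cell and erythroid markers for the stimuli at 3 h (0.0783 and 0.233). Leaving out anti-NK1.1 3 h replicate 2 gave 2 lists for the difference, and the other libraries 1.

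The correlation of the stimuli was 0.716 at 3 h and 0.505 at 6 h with a term for MK, and that of their changes over time was 0.387 with an offset of 0.1 and 0.610 for genes with a mean log2 value of at least 5. Depth differs up to 1.85 against 0.354 between libraries, and low values of the shallow ones move in coarse steps that no setting removes.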

Other observations

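The tests of Ifng between libraries were chosen only after their results were seen. Some genes of the lists moved together with both stimuli in ways the list results do not show. Irf7, the interferon regulatory factor that amplifies type I interferon, fell in all 4 comparisons with unstimulated cells (-3.49 and -3.39 at 3 h and 6 h of IL-12 and IL-18, -2.22 and -2.29 with anti-NK1.1), while the interferon gamma target Gbp2 rose by 1.53 and 1.84 with anti-NK1.1. Lck, the kinase gene, changed by -2.81, -2.47, -1.36 and -1.08 in the same order. Among genes of apoptosis and survival at 6 h, Bcl2l1 rose by 4.48 and 2.01 with IL-12 and IL-18 and with anti-NK1.1. Tnfrsf9, which encodes the costimulatory receptor 4-1BB, rose by 3.40 and 3.16 at 6 h, and Pdcd1, which encodes PD-1, by 2.09 and 1.97 at 3 h.

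Hk2, which encodes hexokinase 2, rose by 3.76 and 3.74 with IL-12 and IL-18, and the glucose transporter gene Slc2a1 changed by -1.50 and -1.70 with anti-NK1.1 and was higher with the cytokines than with the antibody by 1.78 and 2.33. Ccl22, a chemokine gene for CCR4, rose by 5.46 and 5.41 at 6 h with the cytokines and with the antibody.

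In the anti-NK1.1 3 h libraries Ifng stood at 11.50 and 10.64 with MK1 and at 9.19 with MK2. MK1 libraries could hold reads carried over from the IL-12 and IL-18 libraries of that value. For 11 genes raised mainly by the cytokines (Il2ra by both stimuli), MK1 anti-NK1.1 libraries had a median of 3.26% of the cytokine value (spread 0.772). Ifng had 2.25%. The MK2 library had a median share of 4.75%. It should hold no such reads if they pass only between libraries of the same MK value, which no source states. A condition that voids the test for this reason was added after its result was seen, as the first version counted for that explanation. Carried reads thus cannot be told apart from a higher response. The excess over the MK2 library was 1.67% for Ifng against a median of 1.02%, negative for 4 of 11 genes. A weaker response of the MK2 library as a whole stays open too. Its median rise over 152 genes that anti-NK1.1 alone raised was 0.99 against 0.84 and 0.96 in the other two, and its excess of 0.0289 over the larger is within the spread of 0.0849 between the libraries with MK1. Other genes of the response were, like Ifng, highest in replicate 1 and lowest in replicate 3, the MK2 library, with Ccl4 at 13.98, 13.10 and 12.73, Xcl1 at 14.43, 13.53 and 12.98, Csf2 at 5.54, 4.47 and 1.32 and Egr2 at 9.91, 8.97 and 8.57.

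The tests of cell shares were chosen after members of the monocyte list had been seen falling, and 7 of the 27 measured test genes are in that list. With anti-NK1.1 at 6 h their median log2 change was -1.28 (spread 0.241), with 26 of 27 lower and 16 called lower, and in the 20 genes of no fixed list it was -1.31 with 19 lower, so a smaller share of monocytes or macrophages is a candidate explanation that meets what its test needs. At 3 h of anti-NK1.1 the median was -1.75 with 26 of 27 lower, and with IL-12 and IL-18 it was -0.73 with 18 lower at 3 h and -0.91 with 22 lower at 6 h. Of the 27 genes, 7 stood above the median gene in unstimulated cells, among them Cybb at 10.53, Ctss at 9.57 and Lyz2 at 8.26, and NK cells may express part of them. With anti-NK1.1 at 6 h, a smaller share of every other cell type stays open. Dendritic markers fell. The 7 erythroid and platelet markers did not (median 0.0612, spread 0.212) but were called up at 3 h, so they cannot decide it. The 9 T cell markers had a median of 0.26 with a spread of 0.721 over genes that moved both ways, too wide to decide alone, and their mean deviation was 0.65, 0.69 and 0.86 in the libraries at 6 h against 0.06, 0.16 and -0.02 in unstimulated ones (fry adjusted p = 0.013). This was not tested with IL-12 and IL-18, where at 6 h the T and B cell lists had medians of -1.10 and -1.35 (fry adjusted p = 3.28e-07 and 0.00484) and the erythroid list 0.25.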
